A study of Mus musculus with 6 samples.

How the data were processed

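RNA sequencing was carried out on 6 libraries from RAW264.7, a mouse macrophage cell line, 3 treated with phosphate buffered saline (PBS) and 3 with CM-PEG-PLGA@DOX/R848 nanoparticles, all for 24 h. DOX is doxorubicin, a topoisomerase II poison that damages DNA, and R848 is resiquimod, an agonist of Toll-like receptors that include Tlr7. PLGA and PEG are the polymers poly(lactic-co-glycolic acid) and polyethylene glycol, and the labels do not spell out CM. The particle dose was set to carry the equivalent of 2 µg/mL DOX. RNA was isolated with TRIzol and libraries followed a BGI protocol for mRNA with an enrichment step, per the labels' protocols. Each library was placed in its group by its title, and each value column was matched to its library by the library name in the labels. The column matched to PBS replicate 1 adds a suffix to that name, and the meaning of the suffix is not given in the sources used here. The labels number replicates 1 to 3 in both groups and do not say whether these came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

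The deposited table held 1 column of FPKM per library, which the authors had scaled by transcript length and library size. No unit stands in the header, and FPKM was inferred from the values. They were not whole numbers, their sums differed between libraries, and the low values of genes with a single transcript piled up at a common step after multiplication by transcript length. TPM with some rows removed beforehand is not excluded. STAR, featureCounts and the builds GRCm38 and mm10 are named in the submitters' processing notes, with no versions and no normalization. Of the 22614 rows, 22105 carried Ensembl gene identifiers. A further 498 carried MSTRG identifiers, the form used by the assembler StringTie, which those notes do not name, and 11 carried transcript identifiers. These 509 unnamed rows held 0.427% to 0.497% of the FPKM of a library and were left out of the tests. Of the Ensembl identifiers, 21995 were found in GENCODE M21 (GRCm38), which supplied coordinates, gene types, transcript lengths and GC content. Symbols are those of the table. Of the rows found, 21383 were protein-coding genes.

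The total depth is not given in the sources used here. The step of the low values implies 17000000 to 21800000 fragments per library, as an inference. The step was sought only within a preset range, so a depth outside the matching range could not be seen. Only 22.7% to 30.8% of low values were whole multiples of that step within 0.05 of a fragment, so fragment numbers were not recovered and no test of counts was run. A gene listed at 0 is reported as such, and no fold is given against a group at 0. Whether counting used strand is not given in the sources used here, so genes that overlap another gene or share sequence with near-identical copies are treated as uncertain. Among the genes named, Ddit3, Cx3cr1, Ccnd1, Ercc1, Csf1r and Ndufb1 overlap an opposite-strand gene with a mean of at least 10 FPKM.

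Counts of fragments per gene had been planned for. Since the values were FPKM, the test laid down for normalized values was used: log2(FPKM + 1), genes with a mean of at least 1 FPKM over all 6 libraries, limma 3.58.1 with an intensity trend (R 4.3.3), treatment as the only term, two-sided, and Benjamini-Hochberg adjustment with a threshold of 0.05. Fold changes are therefore on the log2(FPKM + 1) scale, which understates the change of low genes, and the order of genes by fold change depends on the pseudocount. Means are given with the SD over n = 3 libraries. Tables were read with Python 3.11.15 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.

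The design, the test, the rule for naming genes and 36 gene lists were chosen before the data were examined. The rule took the 5 genes with the largest fold change in each direction among those past the threshold with a mean of at least 10 FPKM and non-overlapping groups, a fixed set (Tlr7, Tnf, Il1b, Il6, Nos2, Cd80, Cd86, Arg1, Mrc1, Cdkn1a, Mdm2, Top2a, Ifit1 and Cxcl10), and the 2 members of each list with the smallest p-values. The most significant member going against the majority of its list was added where it passed. Some genes taken by this rule are not reported here. Lists with at least 5 tested members, 30 in all, were tested with limma's camera at a preset correlation of 0.01, which asks whether a list moved relative to the other genes, with Benjamini-Hochberg adjustment over the 30. Camera was repeated with the correlation estimated from the data. In that form it rests on the residual degrees of freedom of the fit, which are few with 6 libraries. A block for the replicate number, described below, leaves fewer still. Small p-values are then hard to reach, so a call lost in that form does not show that a list was unmoved. Some genes belong to several lists.

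On simulated values with the spread of these libraries, the gene test ran on 10229 genes of which 200 were changed. It recovered 12% of genes changed 1.2-fold, 78% at 1.5-fold, 90% at 2-fold and 98% at 4-fold, with 1 false call. Of simulated lists with no shift, 2.5% had an unadjusted camera p under 0.05. The noise was drawn independently for each gene, so this share does not cover lists whose genes vary together. In the real lists the estimated correlation reached 0.71, for mitochondrially encoded transcripts. The simulation also changed far fewer genes than were called in the data.

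Whether the replicate numbers pair libraries across the groups was checked from deviations from the group means. Same-numbered libraries correlated at 0.13, 0.11 and 0.35, each above the limit of 0.1, so the numbers were taken to pair the libraries, a reading from the data and not from the labels. The reading is not clear-cut, since PBS replicate 2 and nanoparticle replicate 1 also correlated at 0.13; the other differently numbered pairs were at 0.011 or lower. The deviations followed transcript GC content, with rank correlations across genes of 0.47 and 0.59 in the libraries numbered 1 and -0.42 and -0.55 in those numbered 3. Genes are not independent replicates in these correlations. The fold change itself correlated with GC content at -0.05. The planned test without a block was kept, and the fit with the replicate number as a block was run beside it.

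The alternatives were other scalings, pseudocounts of 0.1 and 10, other filters on low values, the replicate block, correction for GC content and length with and without the block, leaving out each library in turn, limma's treat against a 1.5-fold change, a log2 fold change of at least 1, and other list tests. Correlations of log2 values between libraries of a group were 0.991 to 0.996, and at most 0.0587% of tested values were identical between any 2 libraries, so no library appeared to be deposited more than once.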

Results

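The table covered 6 libraries of RAW264.7 macrophages, 3 given PBS and 3 given CM-PEG-PLGA@DOX/R848 nanoparticles for 24 h. PBS libraries listed 12678 to 12872 genes above 0 FPKM, and nanoparticle libraries 15723 to 15989. The depth implied by the low values was 17800000 to 21800000 fragments in PBS libraries and 17000000 to 18100000 fragments in nanoparticle libraries. The 10 most abundant genes took 9.02% to 10.4% of the FPKM. A first principal component, holding 93.9% of the variance of the tested genes, separated the groups.

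The comparison asks how the transcriptome of the macrophages differed between the particles and PBS. After nanoparticle treatment, inflammatory cytokine, interferon response and p53 target genes were higher as groups, and genes of DNA replication and of cholesterol synthesis and uptake were lower. These list calls, made with a preset correlation, were all lost when the correlation was estimated together with the replicate block (camera adjusted p of 0.19 to 0.22). That form of camera has little power with 6 libraries, so the loss does not show that the lists were unmoved. Of the genes tested, 26 of 27, 57 of 57 and 29 of 36 rose in the higher lists, and 36 of 50 and 19 of 25 fell in the lower ones. Il1b, a pro-inflammatory cytokine, rose from 2.48 ± 0.368 to 308 ± 7.05 FPKM (SD, n = 3). Cx3cr1, the fractalkine receptor, fell from 75.2 ± 1.36 to 1.25 ± 0.0353 FPKM. Tnf fell while 26 other tested cytokine and chemokine genes rose, and Tlr7, a receptor for R848, fell 2.01-fold as a ratio of mean FPKM.

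Of 10229 genes tested with limma, 7896 passed a Benjamini-Hochberg threshold of 0.05, 4366 higher and 3530 lower in nanoparticle libraries. A log2 fold change of at least 1 was reached by 1164 of the higher and 643 of the lower genes, and of at least 2 by 289 and 60. Groups did not overlap at 78.8% of the tested genes, against 10% by chance for 3 against 3. The median log2 fold change was 0.08. Upper quartile scaling moved that median by -0.11, and the share of calls that were higher from 55.3% to 47.3%. The directions of the called lists and of the tested genes taken by the naming rule held under each scaling tried. As no library received a single component, DOX, R848 and the carrier cannot be separated.

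Il1b (ENSMUSG00000027398, chromosome 2, 129364570 to 129371139, GRCm38) rose by a log2 fold change of 6.48 ± 0.08 (SE, limma adjusted p = 2.2e-11). Cd40 (ENSMUSG00000017652, chromosome 2, 165055627 to 165072948), a costimulatory receptor, rose from 2.08 ± 0.550 to 237 ± 19.9 FPKM. Ddit3 (ENSMUSG00000025408, chromosome 10, 127290774 to 127296288), which encodes the stress transcription factor CHOP, rose from 5.36 ± 0.597 to 288 ± 5.67 FPKM. Rsad2 (ENSMUSG00000020641, chromosome 12, 26442746 to 26456452), which encodes the antiviral protein viperin, rose from 1.44 ± 0.143 to 107 ± 10.4 FPKM. Ifit3b (ENSMUSG00000062488, chromosome 19, 34607970 to 34613401) had a log2 fold change of 5.45, but it is nearly identical to Ifit3 and the split of fragments between the pair is uncertain.

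Cx3cr1 (ENSMUSG00000052336, chromosome 9, 119901616 to 120069879) fell, with a log2 fold change of -5.08 ± 0.06 (SE, limma adjusted p = 2.2e-11). Its annotated span overlaps other genes, among them Csrnp1, which was itself higher (log2 fold change 1.68). Kcnn4 (ENSMUSG00000054342, chromosome 7, 24370263 to 24386690), a calcium-activated potassium channel, fell from 81.3 ± 2.03 to 5.01 ± 0.613 FPKM. Ccnd1 (ENSMUSG00000070348, chromosome 7, 144929931 to 144939925), cyclin D1, fell from 182 ± 6.75 to 13.5 ± 0.559 FPKM. Plau (ENSMUSG00000021822, chromosome 14, 20836660 to 20843385), the urokinase-type plasminogen activator, fell from 161 ± 2.40 to 14.3 ± 0.612 FPKM. Pde2a (ENSMUSG00000110195, chromosome 7, 101421691 to 101512827), a phosphodiesterase, fell from 27.5 ± 0.501 FPKM to 4.76, 0.417 and 2.53 FPKM in the 3 nanoparticle libraries. A same-strand gene model, Gm45837, overlaps nearly the whole span of Pde2a, which makes its level uncertain.

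**Figure D1:**
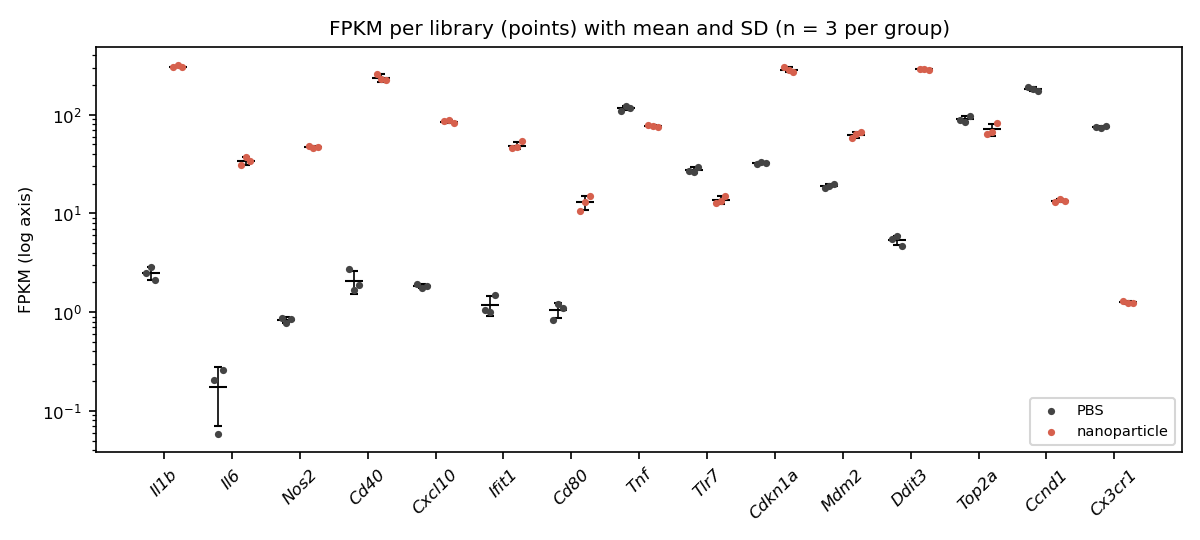
FPKM of 15 genes in each library on a log axis, PBS in grey and nanoparticle in orange; points are libraries, and bars are the mean and SD (n = 3 per group). Il1b reached 308 FPKM in nanoparticle libraries against 2.48 in PBS, while Cx3cr1 fell from 75.2 to 1.25 FPKM.

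Inflammatory genes rose in nearly all tested members. In the list of inflammatory cytokines and chemokines, 26 of 27 tested members rose and 1 fell, with a median log2 fold change of 2.79 (camera adjusted p = 1.7e-10, adjusted p = 0.19 with an estimated correlation and the replicate block). Cxcl10, a chemokine for activated T cells, rose from 1.84 ± 0.0889 to 85.0 ± 3.22 FPKM. Il6 rose from 0.174 ± 0.103 to 34.0 ± 3.19 FPKM. The exception was Tnf (ENSMUSG00000024401, chromosome 17, 35199381 to 35202007), which fell from 116 ± 5.77 to 77.1 ± 2.04 FPKM (log2 fold change -0.59 ± 0.06 SE, limma adjusted p = 6.0e-06). Among NF-kB regulators and feedback genes, 33 of 37 rose and 3 fell (median 1.53, camera adjusted p = 8.9e-09, adjusted p = 0.19 with an estimated correlation and the replicate block). Acod1, which makes itaconate, rose to 136 ± 3.62 FPKM from 10.8 ± 0.694, and the adhesion molecule gene Icam1 rose to 359 ± 19.1 from 44.0 ± 0.600. Irak2, a kinase of Toll-like receptor signalling, fell (log2 fold change -0.46). All 57 tested type I interferon response genes rose, with a median log2 fold change of 2.44 (camera adjusted p = 7.4e-20, adjusted p = 0.19 with an estimated correlation and the replicate block). Isg20, an antiviral exonuclease, rose from 3.99 ± 0.246 to 188 ± 6.91 FPKM, Ifit3 from 1.81 ± 0.222 to 102 ± 4.34 and Ifit1 from 1.18 ± 0.263 to 48.7 ± 4.21.

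Of the 30 lists tested, 19 passed camera's threshold, 12 higher and 7 lower. With an estimated correlation 6 passed, each with an adjusted p of 0.043: the cytokine, NF-kB, interferon, p53, DNA replication and cholesterol lists. With the replicate block as well, all 6 lost the call (adjusted p = 0.22 for the DNA replication list and 0.19 for the others). The few residual degrees of freedom limit this form of the test. Adjusted over the list alone, the numbers of genes higher and lower equalled those over all genes tested except in the glycolysis and nuclear oxidative phosphorylation lists.

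Markers of M1-type activation rose in 12 of 13 tested members, with Tnf as the exception (median log2 fold change 3.54, camera adjusted p = 4.5e-05, adjusted p = 0.061 with an estimated correlation). Nos2, the inducible nitric oxide synthase, rose from 0.835 ± 0.0564 to 46.8 ± 1.28 FPKM. Cd80, a costimulatory ligand, rose from 1.05 ± 0.189 to 12.9 ± 2.23 FPKM. Cd86 was under the expression filter and was not tested, with 0.0712, 0.0973 and 0.0284 FPKM in PBS and 1.48, 1.47 and 1.64 FPKM in nanoparticle libraries. Of 15 tested M2-type markers 10 rose and 3 fell (median 1.02, camera adjusted p = 0.045). That list call depended on the processing. It was lost with an estimated correlation (adjusted p = 0.21), the replicate block (0.070), GC and length correction (0.070, and 0.084 with the block), a pseudocount of 10 (0.051) and without nanoparticle replicate 1 (0.061). Camera kept it in the other alternatives, with an adjusted p of 0.015 to 0.047. Its members with the smallest p-values were Il1rn, the interleukin 1 receptor antagonist, at 479 ± 16.0 FPKM from 26.6 ± 1.00, and the chemokine gene Ccl22, at 93.4 ± 5.29 from 2.14 ± 0.199. Trem2, a lipid-sensing receptor, fell from 230 ± 8.63 to 65.7 ± 9.31 FPKM. Arg1 and Mrc1, classical M2 markers, stayed at or under 0.102 and 0.184 FPKM in every library and were not tested.

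Genes of antigen presentation rose in most tested members. In the MHC class I list 19 of 24 rose and 3 fell (median log2 fold change 1.15, camera adjusted p = 1.5e-04, adjusted p = 0.24 with an estimated correlation). H2-Q4 rose from 19.1 ± 0.975 to 135 ± 4.22 FPKM and H2-T22 from 19.5 ± 1.28 to 84.5 ± 3.33, while H2-T24 fell (log2 fold change -0.63). These class I genes are close paralogs, so their individual values are uncertain. In the MHC class II list 9 of 10 rose (median 0.97, camera adjusted p = 4.7e-03, adjusted p = 0.31 with an estimated correlation). Cd74, the invariant chain, rose from 172 ± 7.77 to 939 ± 52.9 FPKM and H2-Eb1 from 0.144 ± 0.0530 to 10.9 ± 1.84. Rfxap, a class II transcription factor subunit, was lower by a log2 fold change of -0.19 (limma adjusted p = 0.023), a call lost without any 1 of 4 libraries (PBS replicates 1, 2 or 3 or nanoparticle replicate 3; adjusted p of 0.053 to 0.068). Among costimulatory and checkpoint molecules 10 of 17 rose and 5 fell, and the list did not pass (camera adjusted p = 0.11). Tnfrsf9, which encodes the costimulatory receptor 4-1BB, rose from 1.81 ± 0.0911 to 74.9 ± 3.89 FPKM, and Sirpa, an inhibitory receptor, fell from 60.1 ± 0.865 to 28.2 ± 1.27.

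Toll-like receptors and their adaptors moved both ways, 13 of 26 higher and 9 lower (camera adjusted p = 0.77). Tlr3, a receptor for double-stranded RNA, rose from 2.19 ± 0.180 to 20.7 ± 2.91 FPKM. Tlr13 fell from 14.5 ± 0.580 to 2.67 ± 0.294. Tlr7 (ENSMUSG00000044583, chromosome X, 167304929 to 167330558) fell from 27.6 ± 1.93 to 13.7 ± 1.16 FPKM (log2 fold change -0.96 ± 0.08 SE, limma adjusted p = 2.0e-06). Macrophage identity genes also divided, 15 of 34 higher and 16 lower (camera adjusted p = 0.46). Csf1r, the receptor for macrophage colony-stimulating factor, fell from 296 ± 7.93 to 49.1 ± 1.61 FPKM, whereas Adgre1, which encodes the F4/80 antigen, rose from 1.77 ± 0.177 to 12.4 ± 1.16. Among osteoclast differentiation genes 4 of 11 rose and 6 fell (camera adjusted p = 0.49). Tnfrsf11a, the receptor RANK, fell from 14.4 ± 0.688 to 4.28 ± 0.106 FPKM and the protease gene Mmp9 rose from 0.329 ± 0.0941 to 4.54 ± 0.284.

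In the p53 target list 29 of 36 rose and 3 fell, with a median log2 fold change of 0.74 (camera adjusted p = 2.3e-05, adjusted p = 0.19 with an estimated correlation and the replicate block). Cdkn1a (ENSMUSG00000023067, chromosome 17, 29090976 to 29100727), which encodes the cell cycle inhibitor p21, rose from 32.6 ± 0.885 to 286 ± 17.1 FPKM (log2 fold change 3.09 ± 0.06 SE, limma adjusted p = 1.4e-10). Mdm2, the ubiquitin ligase that restrains p53, rose from 19.1 ± 0.771 to 63.0 ± 4.40 FPKM, and the kinase gene Plk3 from 3.71 ± 0.176 to 43.1 ± 1.54. Pidd1, a death domain protein gene, fell (log2 fold change -0.85). DNA repair and checkpoint genes were mostly lower, 32 of 50, with 8 higher (median -0.39, camera adjusted p = 2.0e-04, adjusted p = 0.45 with an estimated correlation). Parp1, a sensor of DNA strand breaks, fell from 86.7 ± 0.151 to 21.1 ± 1.06 FPKM. Ercc1, a nucleotide excision repair subunit, rose from 10.5 ± 0.147 to 44.2 ± 3.54 FPKM, and it overlaps Polr1g on the opposite strand (log2 fold change -0.09).

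Genes of the cell cycle were lower in most cases. Of 50 DNA replication and G1/S genes 36 fell and 6 rose, with a median log2 fold change of -0.60 (camera adjusted p = 3.2e-07, adjusted p = 0.22 with an estimated correlation and the replicate block). Tk1, thymidine kinase, fell from 121 ± 3.90 to 15.2 ± 2.16 FPKM. In the G2/M and mitosis list 25 of 46 fell and 13 rose (median -0.24, camera adjusted p = 0.036, adjusted p = 0.45 with an estimated correlation). The call of that list was also lost without PBS replicate 3 (adjusted p = 0.051) or nanoparticle replicate 1 (adjusted p = 0.060). Bub1b and Mad2l1, of the spindle checkpoint, fell from 70.1 ± 1.74 to 30.5 ± 0.387 and from 54.9 ± 1.65 to 26.7 ± 0.875 FPKM, while the mitotic kinase gene Aurka rose from 85.3 ± 2.73 to 152 ± 5.19. Top2a, the topoisomerase that DOX poisons, fell from 89.9 ± 6.38 to 70.9 ± 9.49 FPKM (log2 fold change -0.34 ± 0.09 SE, limma adjusted p = 6.5e-03).

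Replication-dependent histone genes went the opposite way from the replication list. Of 48 tested, 47 rose and none fell, with a median log2 fold change of 1.98 (camera adjusted p = 4.9e-13, adjusted p = 0.062 with an estimated correlation). Summed over the 68 listed genes, histone FPKM was 59.6 ± 5.74 in PBS and 677 ± 40.7 in nanoparticle libraries (n = 3). H2ac18 rose from 2.69 ± 0.221 to 87.0 ± 11.1 FPKM and H4c9 from 8.06 ± 0.527 to 98.1 ± 7.41. Histone genes are near-identical copies of one another, so single values are uncertain and the sum is the firmer measure.

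**Figure D2:**
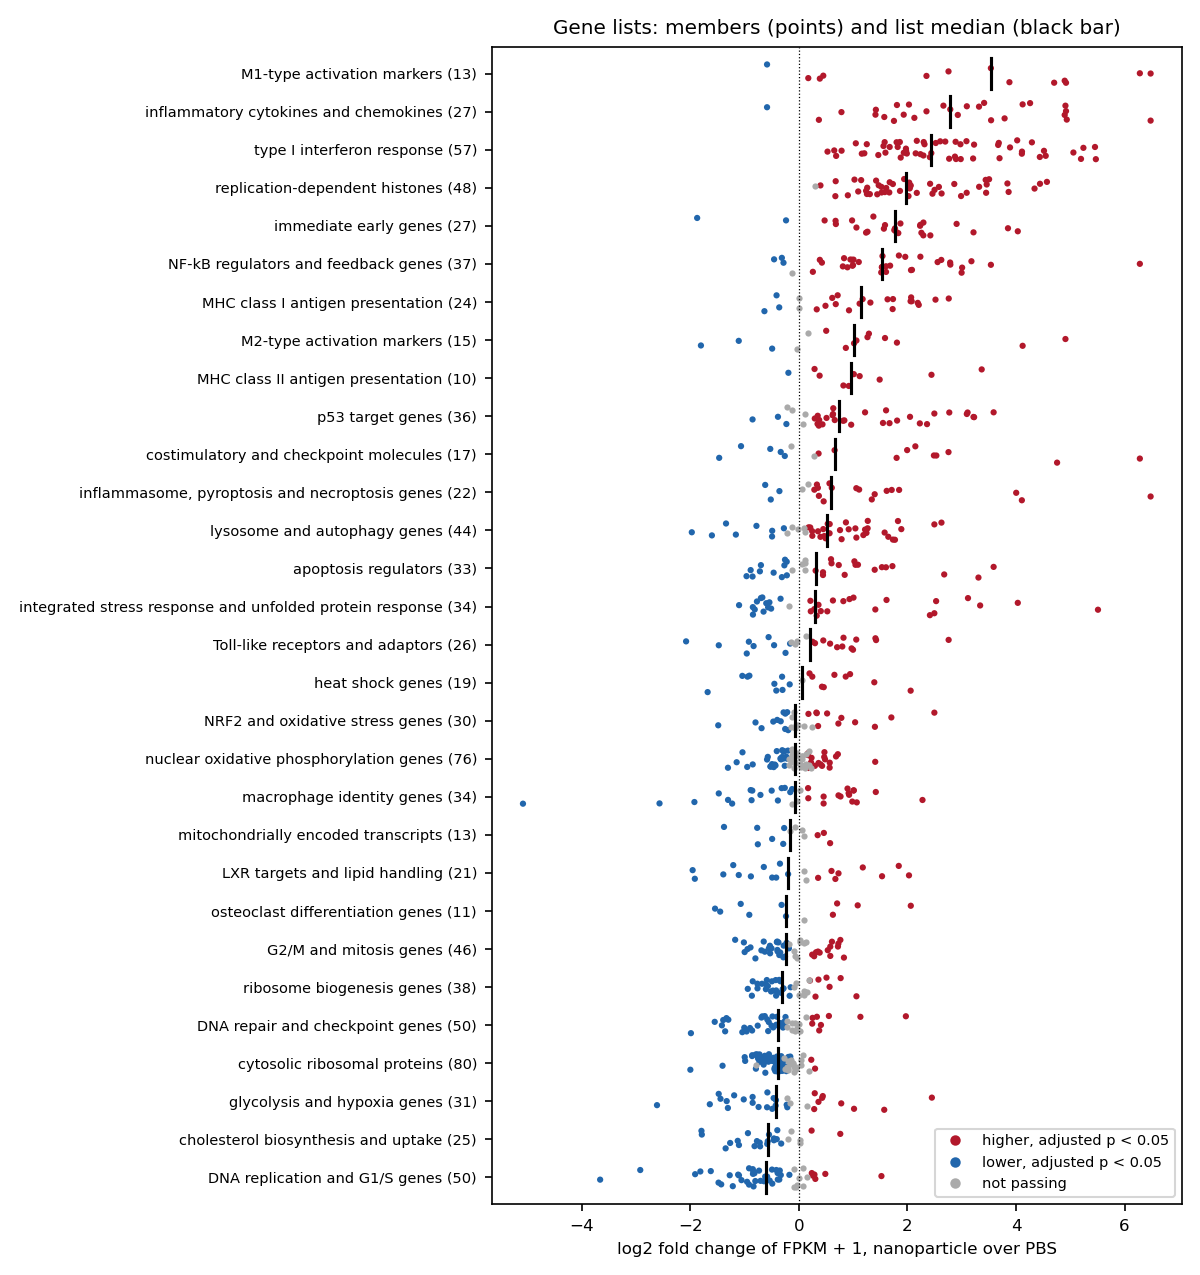
Log2 fold change of FPKM + 1, nanoparticle over PBS, for every tested member of the 30 lists with at least 5 tested members; red and blue points passed the adjusted threshold higher and lower, grey points did not, black bars are list medians and the number tested stands in brackets. The interferon list lies wholly to the right of 0 with a median of 2.44, and the DNA replication list has the lowest median, -0.60.

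Cell death and stress genes did not move as 1 block. Of 33 apoptosis regulators 17 rose and 11 fell (camera adjusted p = 0.20). Bcl2l11, the pro-apoptotic BH3-only gene Bim, rose from 4.42 ± 0.204 to 52.7 ± 1.38 FPKM and Tnfrsf1b from 5.95 ± 0.0807 to 43.5 ± 2.31. In the inflammasome, pyroptosis and necroptosis list 17 of 22 rose and 3 fell (median 0.59, camera adjusted p = 1.0e-03, adjusted p = 0.15 with an estimated correlation). Casp4, the caspase that senses cytosolic lipopolysaccharide, rose from 7.25 ± 0.427 to 131 ± 4.96 FPKM, while Nlrp1b fell (log2 fold change -0.62). Integrated stress and unfolded protein response genes were divided, 20 of 34 higher and 13 lower (camera adjusted p = 0.39). Atf3 rose from 7.89 ± 0.279 to 144 ± 2.81 FPKM, and Psat1, of serine synthesis, fell from 194 ± 2.45 to 108 ± 1.67. NRF2 and oxidative stress genes were evenly split, 11 of 30 each way (median -0.06, mean 0.14, camera adjusted p = 0.82). Sqstm1, the autophagy receptor p62, rose from 89.4 ± 2.86 to 509 ± 28.9 FPKM and Gsr, glutathione reductase, fell from 55.5 ± 0.243 to 19.2 ± 0.562. Of 19 heat shock genes 9 rose and 9 fell (camera adjusted p = 0.70). The median of the heat shock list was 0.06 although camera put it lower, and it was -0.02 after median-ratio scaling. Fkbp4 fell from 229 ± 7.18 to 70.9 ± 2.71 FPKM and Dnajb4 rose from 6.24 ± 0.826 to 29.2 ± 2.83. Immediate early genes rose in 25 of 27 tested members (median 1.77, camera adjusted p = 4.0e-08, adjusted p = 0.062 with an estimated correlation). Btg2 rose from 3.10 ± 0.180 to 37.1 ± 0.330 FPKM and Klf2 fell from 10.5 ± 0.656 to 2.13 ± 0.147.

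Metabolic and organelle genes shifted in several lists. Of 25 genes of cholesterol biosynthesis and uptake 19 fell and 2 rose, with a median log2 fold change of -0.57 (camera adjusted p = 2.1e-05, adjusted p = 0.19 with an estimated correlation and the replicate block). Lpin1, a phosphatidate phosphatase gene, went against the list and rose (log2 fold change 0.76). LXR targets and lipid handling genes were divided, 8 of 21 higher and 11 lower (camera adjusted p = 0.40). Plin2, a lipid droplet coat gene, rose from 113 ± 4.05 to 406 ± 16.7 FPKM and the desaturase gene Scd2 fell from 113 ± 3.47 to 28.5 ± 1.97. Lysosome and autophagy genes rose in 31 of 44 members and fell in 8 (median 0.51, camera adjusted p = 2.9e-03, adjusted p = 0.36 with an estimated correlation). The lysosomal enzyme gene Gla rose from 13.3 ± 0.707 to 87.3 ± 2.65 FPKM.

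Glycolysis and hypoxia genes fell in 19 of 31 members, 20 when adjusted over the list alone, and rose in 9 (median -0.43, camera adjusted p = 0.013, adjusted p = 0.30 with an estimated correlation). Pdk1 fell from 14.1 ± 0.337 to 1.48 ± 0.0982 FPKM and Ndrg1 rose from 23.01 ± 1.30 to 130 ± 4.31. Nuclear oxidative phosphorylation genes moved both ways, 21 of 76 higher, 17 when adjusted over the list alone, and 25 lower (camera adjusted p = 0.20). The balance depended on scaling, with 11 higher and 32 lower after median-ratio scaling, 11 and 38 after upper quartile scaling, and 17 and 44 after GC and length correction with the replicate block. Ndufb1 rose from 31.5 ± 1.02 to 85.7 ± 10.8 FPKM and Atp5mc2 fell from 207 ± 15.2 to 93.2 ± 8.86. The annotation used types the Ndufb1 row as a long non-coding RNA from a bidirectional promoter. It overlaps Cpsf2 on the opposite strand (log2 fold change -0.19), so the rise may not be one of the subunit's mRNA. Of 13 mitochondrially encoded transcripts 6 fell and 3 rose (camera adjusted p = 0.21). mt-Nd3 fell from 196 ± 17.5 to 74.8 ± 6.82 FPKM and mt-Cytb from 3502 ± 149 to 2074 ± 86.3, while mt-Co1 rose from 10142 ± 525 to 13958 ± 687. After correction for GC content and length with the replicate block, the nuclear and the mitochondrial list both passed as lower (camera adjusted p = 1.5e-03 and 3.4e-03), but neither did with an estimated correlation in that fit (adjusted p = 0.44 and 0.24).

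Cytosolic ribosomal protein genes fell in 59 of 80 tested members and rose in 2 (median log2 fold change -0.39, camera adjusted p = 2.0e-08, adjusted p = 0.45 with an estimated correlation). Rps4x fell from 1024 ± 20.98 to 591 ± 2.62 FPKM and Rpl22l1 from 97.4 ± 5.56 to 23.7 ± 1.93. Rpl29 was higher by a log2 fold change of 0.23 (limma adjusted p = 0.017), and lost the call under median-ratio scaling (adjusted p = 0.089), under upper quartile scaling (0.17), after GC and length correction (0.097) and without PBS replicate 2 or 3 or nanoparticle replicate 1 (0.053 to 0.060). Ribosomal protein genes share sequence with many processed pseudogenes, which leaves single values uncertain. Ribosome biogenesis genes fell in 23 of 38 members and rose in 7 (median -0.31, camera adjusted p = 9.9e-03, adjusted p = 0.21 with an estimated correlation). Gar1 fell from 71.9 ± 1.57 to 39.1 ± 1.79 FPKM and Utp4 rose from 64.8 ± 2.10 to 111 ± 1.56.

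Markers of other cell types were scarce. No fibroblast, epithelial and carcinoma, melanocyte, lymphocyte, or erythroid and platelet marker passed the expression filter. The highest single value was 1.88 FPKM, for Muc1 in a nanoparticle library, and Acta2 reached 1.47 FPKM. The mean summed FPKM of each of these lists was low but higher in nanoparticle libraries than in PBS. It was 0.526 in PBS and 2.45 in nanoparticle libraries for fibroblast markers, and 0.113 and 2.24 for epithelial and carcinoma markers. Melanocyte markers summed to 0.327 and 0.595, lymphocyte markers to 0.217 and 0.952, and erythroid and platelet markers to 0.548 and 1.42. These sums were not tested. A rise at low levels was not particular to these markers. Olfactory receptor genes, for example, were listed above 0 in 3.04% of cases in PBS and 14.8% in nanoparticle libraries. Of 15 dendritic cell markers 2 were tested and both rose, Ccl22 and Itgax, the latter from 1.45 ± 0.118 to 5.18 ± 0.334 FPKM.

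**Figure D3:**
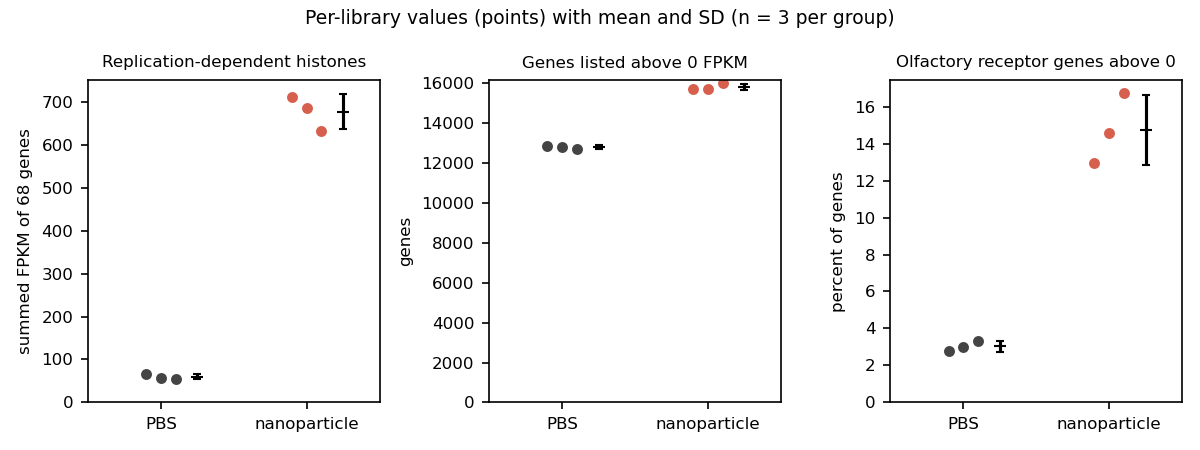
Summed FPKM of 68 replication-dependent histone genes, number of genes listed above 0 FPKM, and percent of olfactory receptor genes listed above 0 FPKM in each library; points are libraries, and bars are the mean and SD (n = 3 per group). Histone sums averaged 59.6 FPKM in PBS and 677 FPKM in nanoparticle libraries, and all axes start at 0.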

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

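The comparison of implied depth and that of silent genes 100 to 500 kb and beyond 500 kb from an expressed gene were tests chosen after the result was seen. Genes outside the main measurement were listed above 0 more often in nanoparticle libraries. Olfactory receptor genes were listed above 0 in 3.04% ± 0.294 of cases in PBS and 14.8% ± 1.89 in nanoparticle libraries (SD, n = 3). For vomeronasal receptor genes the shares were 2.17% ± 0.655 and 14.7% ± 3.75. Mean levels stayed low, at 0.00617 in PBS and 0.0121 FPKM in nanoparticle libraries per olfactory receptor gene, and 0.000887 and 0.00711 per vomeronasal receptor gene. Over all genes, 12789 ± 100 were listed above 0 in PBS and 15812 ± 153 in nanoparticle libraries.

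Greater depth of the nanoparticle libraries is argued against by the low values, since the fragment totals they imply were 0.891 times those of PBS libraries. That holds only if the values are FPKM and the true step lay within the preset range searched. An even background such as genomic DNA would reach silent genes alike, if all of them were equally likely to be counted. The silent genes compared were at 0 in every PBS library and had a longest transcript of 1 to 4 kb. Of 729 within 20 kb of an expressed gene, 48.8% were listed in at least 2 nanoparticle libraries, against 19.9% of 2957 beyond 100 kb. Some of the 729 overlapped the expressed gene, but the 373 downstream and 278 upstream of it were listed at 50.7% and 47.8%. The near over far ratio was 2.45 (95% bootstrap interval 2.21 to 2.73, and 2.45 within 4 classes of transcript length). Among the distant genes the ratio of 100 to 500 kb over beyond 500 kb was 2.00 (1.69 to 2.37). Listing was thus not even over distance. The near and distant genes were not matched for GC content or for sequence shared with other genes. The bootstrap also took neighbouring genes as independent. The ratios therefore cannot decide whether an even background was part or all of the cause. Read-through from expressed neighbours cannot be told apart from other causes, because listing downstream over upstream of the neighbour had a ratio of 1.06 (0.904 to 1.24). Low-level transcription in the treated cells may contribute and was not tested, since treatment and any difference in library handling coincide.

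Of the 509 rows with no gene name, 182 passed the expression filter and were tested beside the named genes. Of these 182, 85 were higher and 25 lower in nanoparticle libraries. For comparison, 4366 of the 10229 named genes tested were higher and 3530 lower in the main test, so the share of higher rows was near that of named genes.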

How the results depend on the processing

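The median-ratio and equal-sum scalings, the filter of 1 FPKM in every library of a group, the GC and length corrections, the inclusion of unnamed rows, limma's treat and the estimated correlation in the unfiltered and the corrected fits were tests chosen after seeing the data. Alternatives set beforehand that need fragment counts (edgeR and DESeq2 normalizations, tests and glmTreat, limma-voom and a filter on counts) were not run. Of 7896 genes called, 2712 passed limma's treat against a 1.5-fold change (1643 higher and 1069 lower), and 1807 also had a log2 fold change of at least 1 (1164 and 643); the stricter thresholds are the cause by construction. Leaving out each library in turn gave 7400 to 7923 genes, 4115 to 4327 higher and 3250 to 3596 lower, and 17 to 19 lists in place of 19. The replicate block, for the pairing of libraries, gave 8351 genes, and among lists it changed only the M2-type call. Camera with an estimated correlation passed 6 lists in place of 19. With the block as well, none passed, and the lowest adjusted p was 0.19. This form of camera is limited to the few residual degrees of freedom of 6 libraries, and the block leaves fewer. For the p53 list the estimated correlation was -0.023, below the preset 0.01, yet its camera adjusted p went from 2.3e-05 to 0.043. The estimate was also below the preset for the DNA replication (-0.0061), cholesterol (0.0041) and M2-type (-0.025) lists. Their camera adjusted p went from 3.2e-07, 2.1e-05 and 0.045 to 0.043, 0.043 and 0.21. A higher correlation is therefore not the cause for the p53 list or for these lists. For the other lists that had passed, the causes were not told apart. Fry, a limma test of whether the genes of a list move, passed 28 lists. The NRF2 list turned from lower to higher with fry, which makes no comparison with other genes (adjusted p = 9.6e-03); its mean and median differ in sign. Of 86 tested genes taken by the naming rule, 83 kept direction and call under all 16 alternatives run on them, and the exceptions were Rfxap, Rpl29 and mt-Co1 (adjusted p = 0.082 for mt-Co1 with no filter on low values). With no filter, 18008 genes were tested and 9804 called, 63.7% of them higher. The costimulatory, mitochondrially encoded and nuclear oxidative phosphorylation lists then passed (adjusted p = 0.042, 0.041 and 7.3e-03), and with an estimated correlation in that fit none of these did (0.15, 0.59 and 0.69).

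The splits of the 6 libraries were compared in a test chosen after the result was seen. Of the 10 splits into 3 and 3, 1, the real one, called as many genes as 7896. The highest of the others called 0 with limma, and between 4 and 46 genes had an unadjusted p under 0.05 in them, against 8063 in the real split. Each of the others mixes the groups, so the treatment difference enters its spread and few calls were bound to follow. They do not show how many genes would be called with no difference between the groups. With 10 splits the share cannot go below 0.1. Among the 4 splits that part all 3 pairs, the others also called 0. In the main test, genes under a mean of 1 FPKM were not tested.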

Other observations

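The symbol families, the replacement histones, the comparisons of summed histone FPKM, of the replication list and of the spread of histone folds, and the median-ratio scaling of the ribosomal genes were tests chosen after the result was seen. Grouped by the stem of their symbols into 110 families of at least 10 tested genes, zinc finger genes with the stem Zfp were higher in 166 of 263 and lower in 31 (median log2 fold change 0.41, camera adjusted p = 4.1e-03). Ifi genes, named for induction by interferon, rose in 14 of 15 (adjusted p = 6.5e-04), and Tnfrsf genes, receptors of the tumour necrosis factor family, in 10 of 11 (adjusted p = 0.030). Genes lower as families were those with the stems Rpl, 40 of 49 (adjusted p = 4.2e-06), and Rps, 23 of 43 (adjusted p = 0.019), the nucleoporins with the stem Nup, 14 of 19 (median -0.44, adjusted p = 5.1e-03), the Myo myosins, 9 of 12 (adjusted p = 0.024), the Dock guanine nucleotide exchange factors, 8 of 10 (adjusted p = 0.046), and Mcm, 8 of 10 (adjusted p = 0.046). None of the families passed with an estimated correlation (adjusted p = 0.94 with an estimated correlation for each family named).

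Variant histone genes outside the replication-dependent list moved apart. H3f3a and H3f3b rose by log2 fold changes of 1.00 and 1.47 and H2aj by 0.67, while H1f0, H2az1, Macroh2a1 and H2ax had log2 fold changes of -1.38, -0.75, -0.63 and -0.45 (limma adjusted p of at most 4.2e-04 for these). H3f3a was uneven in PBS, at 130, 220 and 134 FPKM in replicates 1, 2 and 3, so the size of its rise is uncertain. In nanoparticle libraries H3f3a was at 308 FPKM or more. H2az2 was called higher by 0.34 (adjusted p = 0.035), but its groups overlapped, with 1 nanoparticle library at 15.7 FPKM inside the PBS range of 14.2 to 17.2. The alternative scalings were not run on these variant genes one by one.

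The rise of replication-dependent histone genes was weighed against technical causes. Fragments shifted between near-identical copies would leave the sum unchanged, yet the lowest ratio of summed histone FPKM between any nanoparticle and any PBS library was 9.58. A larger share of cells in S phase might raise the replication list with the histones, but the median log2 fold change of that list was -0.60. The list measures transcript levels and not the phase of the cells, so it cannot decide whether more cells were in S phase. Histone transcripts lacking a poly(A) tail, carried into the nanoparticle libraries, cannot be told apart: folds differed 10.7 times between the 10th and 90th percentile of the 48 genes, where a shared carry-over would predict like folds, but only 6 of them had at least 2 FPKM in every PBS library, so the spread reflects low denominators too. Whether treated cells made more of these transcripts was not tested.

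The decrease of ribosomal protein genes was weighed in the same way. GC content and length differed in effect between libraries, but after correcting for both with the replicate block the median log2 fold change of the 80 genes went from -0.39 to -0.49, with 73 lower. A few abundant genes taking more of the total would end under median-ratio scaling, where the median was -0.47 and 65 were lower. Both argue against those causes as the whole explanation, and a difference in RNA handling between the groups was not tested. A lower level of these transcripts in treated cells may remain as a hypothesis.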
